A study of Homo sapiens with 4 samples.

How the data were processed

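Small RNA was measured in 4 HEK293T libraries, 2 from PGK and 2 from CAG landing pad lines; the group and replicate number of each library came from its sample title. Per the labels' protocols, cells were scraped at sub-confluence, total RNA was isolated with Trizol and an additional chloroform step, and libraries were made with the NEBNext Small RNA kit by core facilities. This kit ligates adapters and amplifies by PCR without molecular identifiers being described, so ligation preference and amplification enter the counts of each miRNA, and levels of different miRNAs are less comparable than levels of 1 miRNA between libraries. The authors deposited whole-number counts in a table of 2656 mature miRNAs and a table of 2094 seed families, with 1 column per library and no pooling. The adapter trimming, aligner, counting rule for reads that fit several miRNAs, annotation and genome build are not given in the sources used here. Totals of the tables differ by at most 19 reads per library, so rounding of estimated counts by the authors cannot be excluded. Every column of both tables belonged to a library of the labels.

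Library totals were 7927615 and 7331437 counts for PGK replicates 1 and 2, and 13780279 and 2845945 for CAG replicates 1 and 2. These totals count reads assigned to miRNAs; the number of sequenced reads is not given in the sources used here. A count of 0 in a library allows a level of up to 0.233 CPM in the deepest and 0.972 CPM in the shallowest library (3 counts). Replicates were compared before averaging: a chi-square statistic of their counts over miRNAs was 81.6 per degree of freedom for the PGK pair and 158 for the CAG pair, far above counting noise, so the libraries of a pair are not copies of the same reads. This does not tell whether they are separate cultures; each library was treated as 1 replicate.

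All tests ran in R 4.3.3. The main test was edgeR 4.0.16 (quasi-likelihood, newer method, robust) on the deposited counts with TMM factors (0.935 to 1.08) and the default low-count filter by group (minimum count 10, minimum total 15), which kept 773 miRNAs holding at least 99.97% of counts and 642 families. The model held the group alone, and the log2 fold change is CAG minus PGK. Its standard error is the fold change divided by the root of the F statistic. P-values were two-sided and adjusted by Benjamini-Hochberg over all miRNAs, or all families, tested; the threshold was 0.05. The common biological coefficient of variation was 0.180. Levels are TMM-normalised CPM, and edgeR's small prior count of 0.125 affects fitted fold changes of miRNAs near 0, for which a pooled count ratio with an exact 95% binomial interval is given instead. Where a group had 0 reads, the fold is a lower bound against 3 counts over that group. Lists were tested with limma 3.58.1 camera (preset correlation 0.01) on log2 CPM with a prior count of 2, beside camera with an estimated correlation and fry, with adjustment over the 25 lists tested. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for permutation tests and figures.

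The design, the alternatives, the 29 lists and the rule for naming miRNAs were fixed before the data were examined, apart from thinning all libraries to the shallowest total and removing a seed GC trend in the families, which were chosen after seeing the data. The lists were the clusters miR-17~92, miR-106b~25, miR-106a~363, HOX miR-10/196, miR-183, 14q32, C19MC, miR-302/367 with miR-371~373, Xq27 miR-506~514, miR-23/27/24, miR-221/222 and miR-99/100 with miR-125. They also held the families let-7, miR-200, miR-15/16, miR-29, miR-30, miR-34/449, miR-181, miR-130/301 and miR-148/152, markers of neural, blood, muscle, mesenchymal and endothelial, and liver, gut and kidney cells, and lists of Drosha-independent miRNAs, entries overlapping other RNA classes, and hypoxia and stress. By the rule, the text names in each direction the 12 called miRNAs with the largest fold change among those with a mean of at least 20 CPM and no overlap between the groups. It also names the 10 most abundant miRNAs, up to 4 of the most abundant tested members of each list described, and 6 families per direction under the same conditions as the miRNAs. Names outside the rule are said to be chosen after their values were seen. A family was tied to miRNAs where their summed counts matched its own within 3 reads in every library.

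The alternatives were RLE, upper-quartile and library size scaling, no filter and a filter of 10 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the older edgeR quasi-likelihood method, the replicate number as a block, each library left out in turn, the 5 most abundant miRNAs removed, and a threshold of 0.01. Hairpin positions come from GENCODE release 29 (GRCh38), matched by name for 2576 of 2656 miRNAs. The build the authors used may differ. No coordinate enters the tests of single miRNAs, families or lists, but the chromosome and X-linked tests group miRNAs by these positions.

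The scripts were tested on simulated counts drawn from the means, dispersions and depths of these libraries. For miRNAs (773 tested) the CAG against PGK test recovered 23.9% of simulated 1.5-fold changes, 50.7% of 2-fold and 98.5% of 4-fold changes, with 8 false calls (6.50% of calls). For families (642 tested) it recovered 43.3%, 61.2% and 97.0%, with 6 false calls (4.29%). Camera called the list that had been shifted and 0 of the others among 23 lists. Each miRNA was drawn independently there, so this does not test false list calls where members are correlated. The replicate chi-square, pooled ratios and correlations describe these 4 libraries only.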

Results

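Small RNA libraries were sequenced from HEK293T cells, a line derived from human embryonic kidney that carries the SV40 large T antigen. The cells carried a landing pad, a genomic site engineered to accept a transgene. In the PGK lines the pad had the PGK promoter, taken from the phosphoglycerate kinase gene. In the CAG lines it had the CAG promoter, a synthetic element built from a cytomegalovirus enhancer and chicken beta-actin sequence. Each group had 2 libraries. The series asked which miRNAs differed in level between lines with one promoter and lines with the other, in a study of how 3′ untranslated regions act on expression. The deposited values were read counts for 2656 mature miRNAs and for 2094 families, each named by its 7-base seed (nucleotides 2 to 8, counted from the 5′ end of the mature miRNA). Total counts were 7927615 and 7331437 in PGK replicates 1 and 2, and 13780279 and 2845945 in CAG replicates 1 and 2. Between 1180 and 1404 miRNAs had a read in each library. A single read was worth 0.0777 CPM (counts scaled to a common library size with TMM factors) in the deepest library and 0.324 CPM in the shallowest, CAG replicate 2. The log2 CPM of the 773 tested miRNAs had a Pearson correlation across miRNAs of 0.990 between the PGK replicates and 0.986 between the CAG replicates. It was 0.953 to 0.962 between libraries of different groups. The lines were monoclonal, and the sources used here do not give the number of lines or whether replicates were separate cultures. P-values therefore measure only the spread between these 4 samples, and promoter and clone cannot be told apart.

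In CAG cells 63 miRNAs were higher and 47 were lower than in PGK cells, out of 773 tested (14.2% called; edgeR quasi-likelihood test, adjusted p under 0.05). The differences reached at least 2-fold for 48 of the higher and 23 of the lower miRNAs. The most different miRNAs came from 1 locus on the X chromosome. miR-105-5p stood at 651 ± 97.1 CPM in CAG and 0.522 ± 0.147 CPM in PGK cells (mean ± SD, n = 2). miR-767-5p stood at 270 ± 23.9 CPM in CAG and 0.188 ± 0.265 CPM in PGK cells (n = 2). miR-218-5p, a miRNA enriched in motor neurons, rose 3.95-fold from 6513 ± 329 to 25715 ± 2205 CPM (n = 2), the highest level among the higher miRNAs with the largest fold changes. miR-34a-5p, whose gene is a transcriptional target of p53, fell by 2.57 on the log2 scale, from 351 ± 3.21 to 58.3 ± 8.23 CPM (n = 2). The called miRNAs together held 14.8% of counts in PGK and 12.6% in CAG cells, and the median log2 fold change over all tested miRNAs was −0.0042. At an unadjusted p under 0.05 the edgeR test counted 208 miRNAs. The count of calls depended on which library was left out. No called miRNA changed sign, but these fits share their libraries with the main fit, so that adds little. Without a PGK library most calls were lost. The lone library was then assumed to vary like the CAG pair, but whether this explains the loss was not tested. The CAG replicates differed more than the PGK replicates. The SD of their log2 differences was 0.419 against 0.357, over miRNAs with a mean of at least 10 CPM. Fewer calls were lost without a CAG library.

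**Figure D1:**
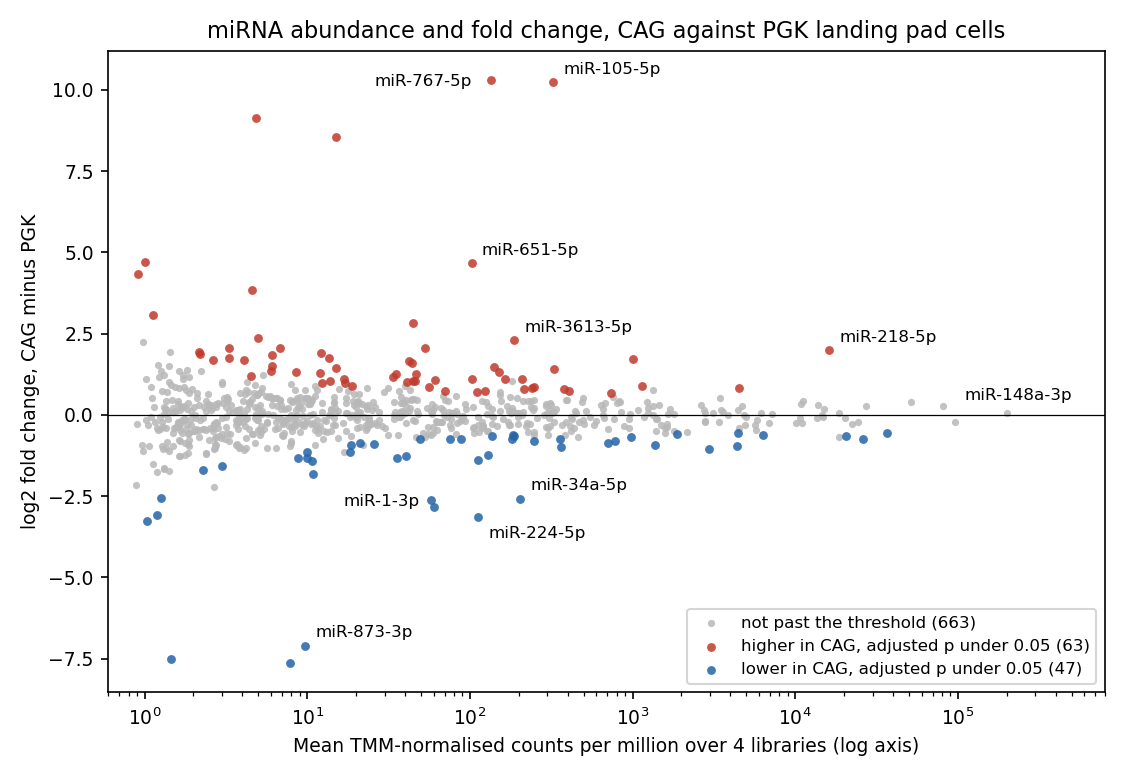
Mean abundance of each of the 773 tested miRNAs (TMM-normalised CPM over the 4 libraries, log axis) against its log2 fold change, CAG minus PGK, with 1 point per miRNA. Red points are the 63 called higher and blue points the 47 called lower in CAG by edgeR; miR-105-5p and miR-767-5p lie at log2 values of 10.23 and 10.30, and miR-148a-3p, the most abundant miRNA, lies at 0.07.

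The miR-105 and miR-767 reads were close to absent from PGK cells. miR-105-5p had 11071 reads over both CAG libraries and 8 over both PGK libraries, a pooled ratio of 1315 (95% exact interval 667 to 3046; edgeR adjusted p = 9.0e-09 for the fitted log2 fold change of 10.23, SE 0.34). For miR-767-5p the numbers were 4470 and 3 reads, a ratio of 1415 (484 to 6866; edgeR adjusted p = 3.3e-08). The other arms of both hairpins, named after their values were seen, moved the same way. miR-105-3p had 521 against 1 read, a ratio of 495 (88.4 to 19585). miR-767-3p had 138 against 0 reads, which made it at least 43.7-fold higher, with 3 reads over the PGK group taken as the limit of a count of 0. The lower end of its 95% exact interval was 35.1. All 3 PGK reads of miR-767-5p came from PGK replicate 1: its ratio was 746 without PGK replicate 2 and at least 669 without PGK replicate 1, and its fitted log2 fold change ran from 9.42 to 14.01 over the alternatives. The ratio of miR-105-3p was 261 without PGK replicate 2 and at least 78.0 without PGK replicate 1, and miR-767-3p was at least 20.7-fold and 23.0-fold higher without PGK replicates 1 and 2. These intervals and limits cover counting error only, because reads amplified without molecular identifiers are not independent molecules. GENCODE release 29 (GRCh38) places MIR105-1 at chromosome X, 152392219 to 152392299, MIR767 at 152393421 to 152393529 and MIR105-2 at 152394412 to 152394492, all on the minus strand in an intron of GABRA3, a GABA receptor subunit gene. The deposited tables hold no coordinates, so each position was looked up by hairpin name. Both copies of MIR105 yield the same mature miR-105-5p and cannot be separated in the counts.

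Further miRNAs rose by smaller factors. miR-651-5p (X, 8126965 to 8127061, plus strand, intron of the antisense gene AC097626.1) went from 7.76 ± 1.06 to 197 ± 9.40 CPM, 25.4-fold (n = 2; edgeR adjusted p = 1.9e-07). miR-3144-3p rose 7.11-fold and miR-6500-3p rose 4.14-fold. miR-3613-5p (13, 49996415 to 49996501, intron of DLEU2) rose 4.90-fold, from 63.9 ± 9.64 to 312 ± 18.5 CPM (n = 2). The remaining higher miRNAs of this kind were miR-1269b at 3.32-fold, miR-199b-5p at 3.18-fold, miR-4421 at 3.02-fold, miR-181a-2-3p at 2.76-fold and miR-576-3p at 2.65-fold. miR-218-5p can arise from MIR218-1 (4, 20528275 to 20528384, intron of SLIT2) and from MIR218-2 (5, 168768146 to 168768255, intron of SLIT3), and the table does not separate them. miR-1269b differs little from miR-1269a, so how reads were shared between these entries is uncertain.

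Among called miRNAs with a mean of at least 20 CPM, the largest declines came from another X-linked pair. miR-224-5p fell by 3.14 on the log2 scale (SE 0.25), from 203 ± 40.7 to 22.2 ± 6.12 CPM (n = 2; edgeR adjusted p = 9.3e-06). miR-452-5p fell by 2.84 (SE 0.22), from 105 ± 3.97 to 14.6 ± 0.514 CPM (n = 2; edgeR adjusted p = 6.6e-06). MIR224 (X, 151958578 to 151958658) and MIR452 (X, 151959628 to 151959712) overlap an exon of an annotated transcript of GABRE, another GABA receptor subunit gene, in GENCODE 29. miR-1-3p, a muscle miRNA with hairpins on chromosomes 18 and 20, fell by 2.61, from 98.9 ± 6.90 to 16.01 ± 0.641 CPM (n = 2). miR-9-3p and miR-9-5p, products of 3 hairpins active in neural precursors, fell by 1.39 and 1.06. miR-192-5p and miR-194-5p, abundant in liver, gut and kidney epithelium, fell by 0.96 and 0.98. The others were miR-1287-5p at −1.33, miR-585-3p at −1.27, miR-4326 at −1.22 and miR-378c at −0.91. Reads of miR-378c may be shared with other miR-378 entries of near-identical sequence.

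Of the 12 largest changes in each direction among called miRNAs with a mean of at least 20 CPM, 8 of the higher and 4 of the lower stayed called under all 15 alternatives of test, scaling, filter and sample that apply to single miRNAs. The 8 were miR-105-5p, miR-767-5p, miR-651-5p, miR-3144-3p, miR-3613-5p, miR-6500-3p, miR-218-5p and miR-1269b. The 4 were miR-224-5p, miR-452-5p, miR-1-3p and miR-34a-5p. miR-199b-5p and miR-9-3p lost the call without PGK replicate 2 (adjusted p = 0.115 and 0.108, edgeR). The other 10 lost it when PGK replicate 1 was left out and when PGK replicate 2 was left out.

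**Figure D2:**
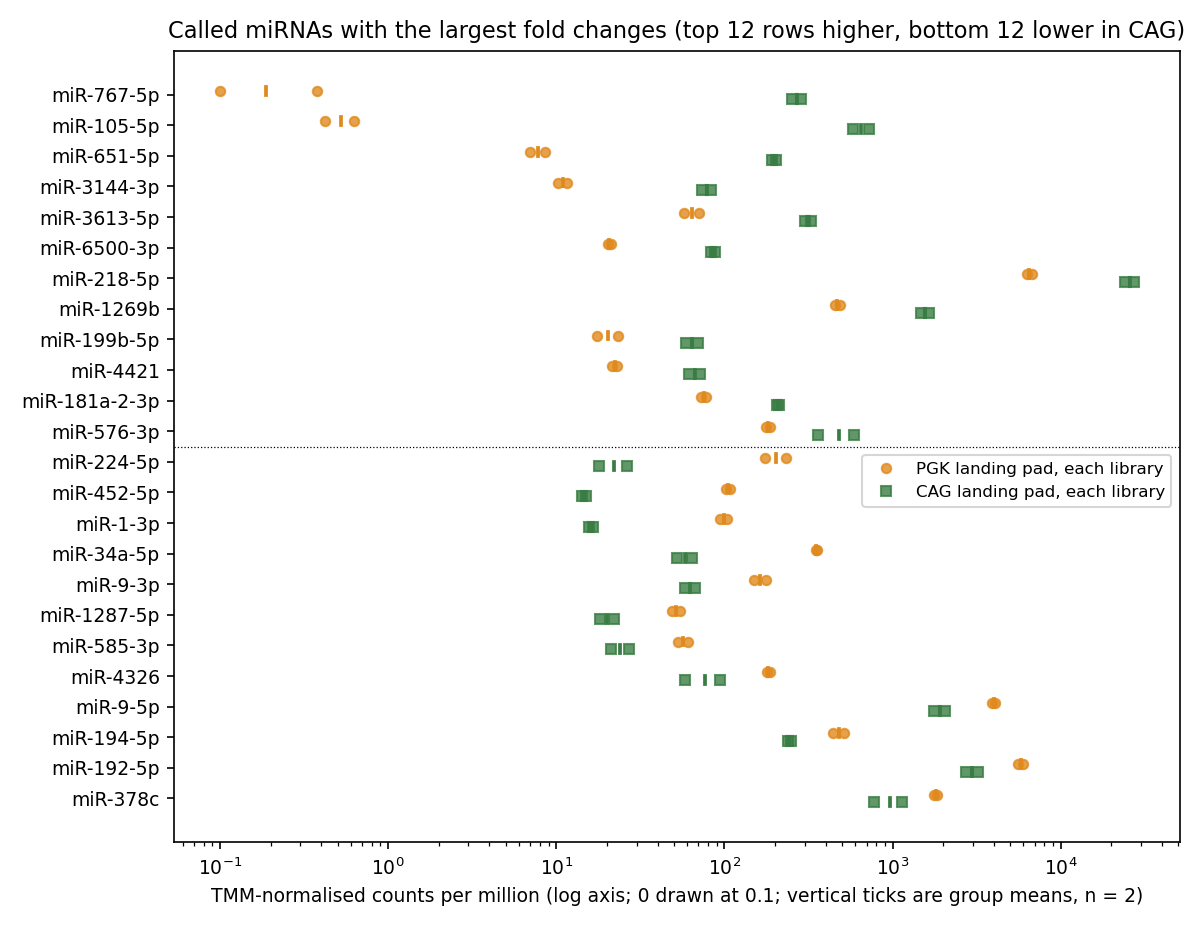
TMM-normalised CPM (log axis) of the 12 higher and 12 lower miRNAs with the largest fold changes among those called with a mean of at least 20 CPM. Each circle is a PGK library, each square a CAG library and each vertical tick a group mean (n = 2), with 0 drawn at 0.1; miR-651-5p sits at 7.76 CPM on average in PGK and 197 CPM in CAG cells, and miR-452-5p at 105 and 14.6 CPM.

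Most of the abundant miRNAs did not pass the test, and neither did most of all 773 tested miRNAs, of which 14.2% were called. miR-148a-3p alone took 18.6% to 21.8% of counts in each library and the 10 most abundant miRNAs took 57.7% to 60.3%. The mean of miR-148a-3p was 194234 ± 5097 CPM in PGK and 204332 ± 41550 CPM in CAG cells (n = 2), a log2 fold change of 0.07 (SE 0.15). miR-92a-3p, miR-10a-5p, miR-10b-5p, miR-151a-3p and miR-25-3p had log2 fold changes of −0.22, 0.28, 0.27, −0.22 and −0.27 and were not called. miR-7-5p was at 76662 CPM in CAG replicate 1 and 41487 CPM in CAG replicate 2, against 47543 and 41262 CPM in PGK replicates 1 and 2, and was not called either. Without CAG replicate 2, miR-7-5p, miR-10a-5p and miR-10b-5p were called higher (log2 fold changes of 0.79, 0.34 and 0.39). Of the 10 most abundant miRNAs, 3 were lower in CAG cells. miR-378a-3p, which lies in an intron of PPARGC1B, fell by 0.55 (SE 0.14), miR-221-3p fell by 0.74 (SE 0.15) and miR-30d-5p fell by 0.66 (SE 0.19), with edgeR adjusted p-values of 0.0249, 0.0093 and 0.0414. All 3 lost the call when PGK replicate 1 was left out and when PGK replicate 2 was left out (edgeR, adjusted p up to 0.319), and with the replicate block; miR-378a-3p and miR-30d-5p also lost it without the low-count filter, and miR-30d-5p with upper-quartile scaling.

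Among seed families, 37 were higher and 30 lower in CAG cells, out of 642 tested (edgeR, adjusted p under 0.05), and 51 of these 67 differed at least 2-fold. With a mean of at least 20 CPM, the same loci led. The family with seed GCACCAU had the counts of miR-767-5p, CAAAUGC those of miR-105-5p, UUAGGAU those of miR-651-5p, UAUACCU those of miR-3144-3p, GUUGUAC those of miR-3613-5p and CACUUGU those of miR-6500-3p. Their log2 fold changes were 10.27 for GCACCAU, 10.20 for CAAAUGC, 4.63 for UUAGGAU, 2.26 for GUUGUAC and 2.01 for CACUUGU, and UAUACCU rose 6.94-fold. On the lower side, CAAGUCA had the counts of miR-224-5p and fell by 3.17, UAAAGCU those of miR-9-3p and fell by 1.43, and GCUGGAU those of miR-1287-5p and fell by 1.37. UAAAGCU lost its call without PGK replicate 1 and without CAG replicate 1 (edgeR adjusted p up to 0.0968), and GCUGGAU lost it with the replicate block and without PGK replicate 1, PGK replicate 2 or CAG replicate 1 (up to 0.102). GGAAUGU, within 3 reads of miR-1-3p in every library, fell by 2.65. GGCAGUG, whose counts matched the sum of miR-34a-5p, miR-34c-5p, miR-449a and miR-449b-5p within 3 reads, fell by 2.35, from 374 ± 0.281 to 72.7 ± 10.96 CPM (n = 2; edgeR adjusted p = 0.000114). ACUGUUU, whose counts matched the sum of miR-452-5p, miR-4676-3p and miR-892c-3p, fell by 2.28. Of the tested families 501 had counts identical to a single miRNA in every library, so the family test is not independent evidence; 52 of these were called, each also as a miRNA. Without PGK replicate 1, PGK replicate 2 and CAG replicate 1 the family counts were 8, 11 and 13 higher and 6, 7 and 10 lower, and library size scaling alone gave 56 higher.

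Among 29 lists of clusters, families, cell-type markers and biogenesis classes fixed before the data were examined, 25 had at least 3 tested members, and 2 ranked above the other miRNAs in CAG cells (camera, preset correlation 0.01). Members of a list can be arms of the same hairpin or neighbours at the same locus, so they are not independent readings. In the miR-181 family 7 of 8 tested members rose, 8 adjusted over the list alone, with a median log2 fold change of 1.04 (camera adjusted p = 0.000111, but adjusted p = 0.857 with an estimated correlation). Among the risers miR-181b-2-3p, named after its values were seen, had only 28 reads in CAG and 3 in PGK cells. miR-181b-5p rose 1.58-fold, miR-181a-5p 1.67-fold, miR-181a-3p 1.76-fold and miR-181d-5p 2.52-fold. In the list of miR-99, miR-100 and miR-125, whose genes are clustered with let-7 genes, 4 of 8 rose, 5 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 0.0088, but adjusted p = 0.857 with an estimated correlation). Its risers were miR-99a-5p at 1.78-fold, from 3251 ± 87.7 to 5797 ± 312 CPM (n = 2), miR-125b-5p at 1.83-fold, miR-100-5p at 2.07-fold and miR-125b-2-3p at 1.67-fold. The last 3 of these 4 were named after their values were seen. The call of miR-99a-5p was lost in 2 of 15 alternatives. miR-99b-5p, miR-125a-5p and miR-99b-3p had log2 fold changes of 0.33, 0.26 and 0.56 and were not called. With an estimated correlation camera called no list (1 at an unadjusted p under 0.05). That version has only the few residual degrees of freedom of these libraries, so hardly any list could pass. Its lack of calls therefore decides nothing about these lists. fry, which tests whether members move one way on balance, gave adjusted p = 0.0096 for miR-181 and 0.0180 for miR-99/100 and miR-125. Without PGK replicate 1 the miR-99/100 and miR-125 list had a camera adjusted p = 0.139, and the 4 named miR-181 members lost their calls when either 1 of the PGK libraries was left out, and miR-181a-5p and miR-181b-5p also with the replicate block. Camera called no list lower in CAG cells (3 at an unadjusted p under 0.05), and fry called the muscle list lower.

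Markers of other cell types moved in both directions. In the neural-enriched list 3 of 10 tested members were higher and 2 lower, with the same counts adjusted over the list alone: miR-218-5p, miR-129-5p (1.73-fold) and miR-132-5p (1.63-fold) rose and both miR-9 arms fell, while miR-128-3p had a log2 fold change of −0.07. In the muscle-enriched list miR-1-3p and miR-133a-3p fell and miR-499a-5p was not called (0.20), also with 2 lower adjusted over the list alone; miR-133a-3p had 34 reads in PGK and 4 in CAG cells, a ratio of 8.95 (95% exact interval 3.19 to 34.7; at least 2.31 without CAG replicate 1). The muscle list had a camera adjusted p = 0.148 and a fry adjusted p = 0.0479. In the mesenchymal and endothelial list miR-199b-5p and miR-143-3p (by 1.32) rose and miR-126-5p fell by 0.89 among 7 tested, with 4 higher and 2 lower adjusted over the list alone; the most abundant member, miR-126-3p, had a log2 fold change of −0.50 and was not called. In the liver, gut and kidney list miR-192-5p, miR-194-5p and miR-194-3p fell and miR-204-5p (3.34-fold) rose among 6 tested, with the same counts over the list alone, and miR-215-5p had a log2 fold change of 0.03 (SE 0.18). None of 3 blood-cell members was called by edgeR, DESeq2 or limma-voom (1 at an unadjusted p under 0.05), and miR-486-5p stood at 0.22. miR-132-5p, miR-143-3p and miR-204-5p were named after their values were seen. Without PGK replicate 2, the calls of miR-9-5p, miR-129-5p, miR-133a-3p, miR-126-5p, miR-192-5p and both miR-194 arms were lost, as they were without PGK replicate 1. Over the 15 alternatives the call was lost in 7 for miR-194-3p and 4 for miR-126-5p, and for miR-133a-3p in 3 of the 12 that tested it.

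Other lists held 1 to 3 called members. In the miR-200 family, expressed in epithelia, miR-200c-3p rose 2.05-fold and miR-200b-3p fell by 1.82, while miR-200a-3p, at −1.74, was not called (edgeR adjusted p = 0.0792). Adjusted over the list alone, 1 was higher and 2 lower. Levels were low: miR-200c-3p, miR-200b-3p and miR-200a-3p had means of 45.0, 10.9 and 1.19 CPM over the libraries. In the miR-15/16 family miR-503-5p and miR-424-5p, neighbours on the X chromosome, fell by 0.85 and 0.75 and miR-16-1-3p rose 1.96-fold, among 13 tested (1 higher and 3 lower over the list alone), while miR-16-5p had a log2 fold change of 0.05. In the miR-30 family miR-30d-5p and miR-30b-5p, neighbours on chromosome 8, fell by 0.66 and 0.80 among 11 tested, 2 also over the list alone, and miR-30a-5p, miR-30c-5p and miR-30e-3p were not called (−0.40, −0.31 and 0.06). miR-34a-5p alone was called among 6 miR-34 and miR-449 members, with 1 higher and 1 lower over the list alone; miR-449c-5p had a log2 fold change of 0.89, called in 2 of 15 alternatives, and miR-34c-5p of −0.52. Among 4 members of the miR-221 and miR-222 cluster miR-221-3p was called, and 3 were lower over the list alone; miR-222-3p had a log2 fold change of −0.67 (edgeR adjusted p = 0.0571) and was called lower in 6 of 15 alternatives, DESeq2 and limma-voom among them. In the hypoxia and stress list miR-146b-5p and miR-193a-5p fell by 0.80 and 0.87 among 12 tested, 2 also over the list alone (DESeq2 called 1), and miR-21-5p and miR-210-3p were not called (−0.11 and −0.14). miR-130b-3p fell by 0.63 among 8 miR-130 and miR-301 members and miR-23a-3p fell by 0.73 among 10 miR-23/27/24 members; neither was called over the list alone. The call of miR-130b-3p was lost in 8 of 15 alternatives, that of miR-146b-5p in 6, that of miR-30d-5p in 5 and that of miR-503-5p in 4; miR-23a-3p lost its call with library size scaling and with upper-quartile scaling. miR-424-5p, miR-16-1-3p, miR-30b-5p, miR-193a-5p and miR-23a-3p were named after their values were seen. When either 1 of the PGK libraries was left out, the named calls of these lists were lost, except miR-34a-5p; for the miRNAs named after their values were seen, that was not worked out one by one.

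Several lists had no called member with edgeR, DESeq2 or limma-voom. No member was called among 11 of the miR-17~92 cluster, 6 of miR-106b~25, 3 of miR-106a with miR-363, 5 of miR-183 or 11 Drosha-independent miRNAs, nor at an unadjusted p under 0.05. Here miR-20a-5p had a log2 fold change of −0.10, miR-93-5p −0.32, miR-106a-5p −0.23, miR-183-5p −0.17 and miR-320a-3p 0.04. The let-7 family had 0 of 17 called and 5 at an unadjusted p under 0.05, with a median of 0.41 and a camera adjusted p = 0.0835; let-7f-5p stood at 0.29 and let-7g-5p at 0.42. The let-7 list was called higher with the replicate block (camera adjusted p = 0.0484) and without PGK replicate 2, and 1 member was called with library size scaling alone. With all libraries and no block, camera with an estimated correlation gave it an adjusted p = 0.857 and fry an adjusted p = 0.159. With so few libraries the first of these could hardly call any list. HOX-cluster miRNAs (miR-10, miR-196 and miR-615) had 0 of 11 called and 4 at an unadjusted p under 0.05. The miR-29 family had 0 of 5 called and 1 unadjusted, and the miR-148 and miR-152 family 0 of 6 and 2 unadjusted. Few members of clusters with little expression in these cells were tested: 1 of the 14q32 cluster (miR-381-3p at 1.15, with a mean of 1.87 CPM), 2 of miR-506 to miR-514 on Xq27 (miR-514a-3p at −0.02), and 0 of C19MC and of miR-302 and miR-367 with miR-371 to miR-373. miR-381-3p had an unadjusted p under 0.05 but was not called (edgeR adjusted p = 0.178). With 1 tested member, adjustment over the list alone leaves its unadjusted p as it is. In the list of entries whose reads can be fragments of other RNA classes, 1 of 10 rose, also over the list alone: miR-5100 at 2.15-fold, named after its value was seen. With library size scaling alone no member of that list was called, and miR-5100 stood at 93.2 and 188 CPM in CAG replicates 1 and 2. The summed level of that list was 5692 CPM in CAG replicate 1 and 13895 CPM in CAG replicate 2, against 9167 and 8838 CPM in PGK replicates 1 and 2. miR-1260b and miR-1260a, its most abundant members, were not called with all libraries (0.16 and 0.08) and had log2 fold changes of −0.66 and −0.73 without CAG replicate 2, and of 0.69 and 0.61 without CAG replicate 1.

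**Figure D3:**
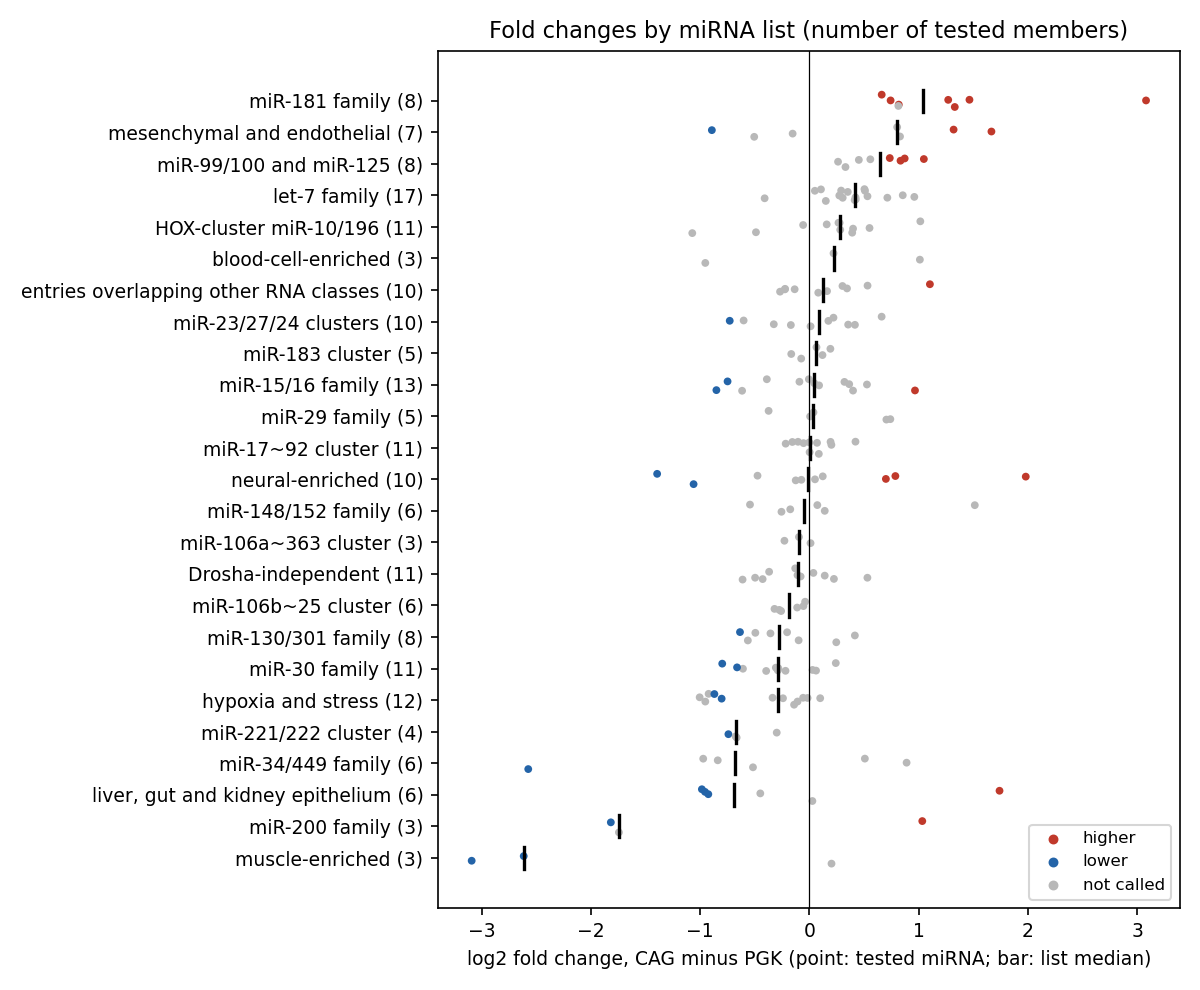
Log2 fold changes, CAG minus PGK, of the tested members of the 25 lists with at least 3 tested members, with 1 point per miRNA (red called higher, blue called lower, grey not called by edgeR) and a black bar at each list's median. The number of tested members follows each list's name; the miR-181 median lies at 1.04 and the muscle-enriched median at −2.61, over 3 members.

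Both arms were tested for 178 miRNA names, paired by name; some names, such as miR-9, miR-105, miR-181a and let-7a, stand for several hairpins. Across names, which are not independent replicates, the log2 fold changes of the 5p and 3p arms had a Pearson correlation of 0.899 and a Spearman correlation of 0.598. Among the 174 names with both arms below 16-fold the Pearson correlation was 0.515, so the higher value rested on a few names such as miR-105. For 10 names both arms were called and all 10 pairs moved in the same direction. For 27 names 1 arm was called, and the other arm had the same sign in 23.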

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

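Thinning and seed GC removal were added after the data were seen. All other settings were planned. The named calls counted next include 6 higher and 6 lower families. Their counts are close to those of called miRNAs or to sums that hold them, so the same signals enter more than once. The miRNAs kept under every alternative are only those listed in Results. Of 53 named calls, 22 kept direction and threshold under every alternative run and 31 lost the threshold in at least 1, of which 18 only when a PGK library was left out; of 78 named values not called, 19 were called under some alternative. Counts of higher and lower miRNAs (63 and 47) and families (37 and 30) changed most when a PGK library was left out, and 91 of 110 miRNA calls were lost without PGK replicate 1, 93 without PGK replicate 2, 33 without CAG replicate 1 and 5 without CAG replicate 2, with no change of sign. Leaving out 1 library gave 10 to 84 higher and 6 to 78 lower miRNAs, 8 to 37 higher and 6 to 23 lower families, 1 to 3 called lists and an arm correlation of 0.781 to 0.840. Such fits share their libraries with the main fit, so an unchanged sign adds little. With 1 library in a group the spread comes from the other group alone. The CAG pair, the only source without a PGK library, differed more than the PGK pair (SD of log2 differences 0.419 against 0.357). Whether this difference accounts for the lost calls was not tested. Without CAG replicate 2 miR-1260b and miR-1260a reversed to −0.66 and −0.73, and without CAG replicate 1 they stood at 0.69 and 0.61, past the edgeR threshold each time. The filter of 10 CPM, which tests fewer miRNAs, gave 39 higher miRNAs, and library size scaling alone gave 56 higher families, for which the cause was not tested. An adjusted p under 0.01 left 32 higher and 17 lower miRNAs and 20 higher and 13 lower families, as a stricter threshold must. Camera with an estimated correlation called 0 lists, but with so few libraries it could hardly call any. Thinning to the shallowest library's 2845945 counts gave 42 higher and 34 lower miRNAs and 40 and 37 families. DESeq2 gave 43 higher and 42 lower miRNAs and limma-voom 63 and 50. No scaling moved the median log2 fold change of all miRNAs by 0.1, but TMM and RLE factors place most changes near 0 by construction. Relative counts cannot show a change in the total amount of miRNA. Small changes were often missed in simulation, with a 2-fold recovery of 50.7%, and depth was not varied there.

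The replicate numbers are shared by both groups, but deviations of same-numbered libraries from their group means had a correlation across miRNAs of −0.0153 (773 miRNAs; 0.0403 over the 436 with a mean of at least 10 CPM), so the numbers are not read as pairs. With the replicate number as a block, 40 higher and 23 lower miRNAs, 14 higher and 7 lower families and 3 lists were called, with let-7 added (camera adjusted p = 0.0484). These list calls used the preset correlation. Camera with an estimated correlation, run without the block, called none of the 3 (adjusted p = 0.857 for each). With so few libraries it could hardly call any list, so this does not decide between them.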

Other observations

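The chromosome tests on ranks and without the loci over 16-fold and the simulated GC bias were chosen after the result was seen, and the seed GC correction after the data were seen, as were all miRNAs named here outside the fixed rule. Beyond miR-105 and miR-767, further miRNAs called by edgeR had 10 or fewer reads in one group (2 libraries per group). miR-873-3p had 291 reads in PGK and 2 in CAG cells, a ratio of 153 (95% exact interval 42.0 to 1271), and miR-873-5p had 238 and 1, a ratio of 251 (44.5 to 9937); GENCODE 29 places MIR873 at chromosome 9, 28888879 to 28888955, with no host gene. Without CAG replicate 1 these were at least 19.7 and 16.1. miR-383-5p had 44 reads in PGK and 0 in CAG cells, at least 15.4-fold lower in CAG with 3 reads over the group as the limit, and at least 2.98-fold without CAG replicate 1. In the other direction miR-511-5p had 171 reads in CAG and 10 in PGK cells, a ratio of 16.2 (8.62 to 34.5), and miR-548ba had 34 and 1, a ratio of 32.3 (5.42 to 1313). The ratio of miR-511-5p was 7.37 without CAG replicate 1, 38.4 without PGK replicate 1 and 10.7 without PGK replicate 2, and that of miR-548ba was 15.3 without PGK replicate 1 and at least 5.67 without PGK replicate 2.

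Some neighbouring miRNAs moved together and others did not, in pairs picked after their values were seen; how often neighbours agree was not counted. miR-216b-5p and miR-217-5p, both in introns of MIR217HG on chromosome 2, rose 3.57-fold and 3.21-fold, and miR-708-5p and miR-5579-3p, both in TENM4 introns on chromosome 11, fell by 0.76 and 1.71. miR-6500-3p and miR-4421, whose hairpins lie at 51060018 to 51060103 and 51059837 to 51059905 on chromosome 1, rose 4.14-fold and 3.02-fold. By contrast miR-585-3p, in an intron of SLIT3, fell by 1.27 although miR-218-5p, which MIR218-2 in SLIT3 and MIR218-1 in SLIT2 both encode, rose by 1.98. In DLEU2, miR-3613-5p and miR-16-1-3p rose by 2.29 and 0.97, while miR-15a-5p stood at 0.36 (SE 0.22) and was not called. miR-192-5p fell by 0.96, whereas miR-215-5p, of related sequence but another locus, stood at 0.03. Whether such neighbours differ from each other was not tested.

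In GABA receptor genes of the X chromosome, the GABRA3 miRNAs rose and the GABRE miRNAs fell. A change in copy number of the whole X chromosome would shift X-linked loci one way, so the opposite directions alone argue against it as the cause of both moves. The median of 16 other X loci was 0.205 on the log2 scale (bootstrap interval −0.198 to 0.468, with 10 above and 6 below 0). That is far under the smaller of the host moves, 2.99. The interval does not exclude a small shift of the whole chromosome beside those moves. RNA from another cell type in the CAG libraries stays open: the smallest camera adjusted p among marker lists pointing upward was 0.539, and the bound set beforehand, that no such list passes, was too weak, since a missed threshold over lists of 3 to 10 members does not bound a shift and germ cells were not listed. The promoter and a difference between clones are both biological candidates that this design cannot separate, and neither was tested. Only 3 splits of the 4 libraries exist, too few for a share under 0.05: the real split gave 110 calls, the highest other split gave 0 (10 and 6 miRNAs at an unadjusted p under 0.05), so that of the 3 splits only 1, the real one, reached that number.

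A candidate explanation for some of the smaller changes is gain or loss of whole chromosomes between lines, which HEK293T cells tolerate. Over 259 loci (391 miRNAs with at least 10 CPM, merged within 10 kb, 23 chromosomes) the between-chromosome sum of squares had a permutation p of 0.173. The bound set beforehand, a p of 0.05 or more, was met but is a poor guide, because 2 loci over 16-fold dominate the sum: on ranks the permutation p was 0.00509, and without those loci it was 0.0233. No chromosome passed alone; the smallest adjusted p was 0.0874, for chromosome 10 with a median of −0.51 and 2 of 13 loci above 0. Whether chromosome-wide shifts contribute cannot be told apart from locus-by-locus changes with these tests.

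Changes below 2-fold might reflect a base composition bias of library preparation. Removing each library's trend on seed GC kept 15 of the 16 family calls below 2-fold, with a median absolute log2 fold change of 0.75 before and 0.73 after, and fold changes had a Spearman correlation with seed GC of −0.031 over 642 families. In simulated counts with no true change and a bias of 0.5 per GC base, the same step removed all 85 false calls below 2-fold. That bias had the form the step subtracts, so the simulation shows only that the step works on such a bias. The near-absent trend in the data, after whose removal the calls were kept, argues against a shift shared by families of equal seed GC as their cause. The composition of the whole miRNA, its ends and the ligation step remain open, as does a difference between the lines.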
